A study of Mus musculus with 2 samples.

How the data were processed

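The data were RNA-seq libraries of polyA RNA from GFP+ cells of the inguinal stromal vascular fraction of male mice, 1 library for Sox9 floxed and 1 for Sox9 PreASKO animals. Per the labels' protocols, tissue was minced and digested with collagenase, cells were stained with an antibody against PDGFRa for flow cytometry, RNA was extracted with a Trizol reagent and libraries were prepared on an automated instrument after selection of mRNA on magnetic beads. The labels do not say how the PDGFRa stain was used for these libraries. Groups were taken from the genotype label of each sample, and table columns were matched to samples by the words KO and WT in the sample titles.

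The authors deposited a table of 24862 genes that, per the file headers, holds a raw count and a repeat-distributed count per gene and library, the authors' fold change and its log2. The genome build was mm10, per the submitters' processing notes. The aligner and the counting program are not given in the sources used here. The raw counts deposited by the authors are whole numbers. The repeat-distributed columns deposited by the authors are estimated counts, and 99.7% of their values lie within 0.01 of a whole number. Of genes past the count filter with 1 RefSeq transcript, 88.3% had raw counts alone and 3.31% repeat-distributed counts alone, against 7.04% and 40.9% of genes with 2 or more transcripts. The columns were therefore read as reads that fit several annotated sequences, mostly transcripts of the same gene, an inference and not a documented definition. They make up 49.1% of floxed and 50.6% of PreASKO counts. Of the listed genes, 42.9% had raw counts alone and 27.6% repeat-distributed counts alone. The authors' deposited fold ratio is PreASKO over floxed, per the file headers, and the deposited log2 column is its logarithm. For 78.6% of the 14606 genes with 20 or more counts in both libraries, the sum of both counts scaled by library total gave the authors' log2 fold within 0.01, which did not hold for Meis1. The table lists no gene with 0 in both libraries before rounding, so genes without reads were left out of it. In 24 cases a spreadsheet had turned a gene symbol into a date, and 48 entries shared a symbol with another entry. These entries were kept in totals and in counts of genes, and none was named. Symbols were matched to gene coordinates of GRCm38.p6 in RefSeq by gene ID, which succeeded for 93.3% of entries, and that annotation may differ from the one the authors used.

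Raw and repeat-distributed counts were summed per gene and rounded to whole numbers. The totals were 37705236 for the floxed and 29172653 for the PreASKO library. Libraries were scaled by TMM in edgeR 4.0.16 under R 4.3.3, with factors of 1.01 and 0.988. Folds are on the log2(CPM + 1) scale, which understates differences of low genes, and ratios are of CPM without a pseudocount. Genes needed 10 or more counts in at least 1 library, which left 18911. With 1 library per group there is no test between genotypes, so no p-values were computed and differences are described. The interval of a ratio is the exact conditional (Clopper-Pearson) interval for a pair of counts and the interval of a level is the exact Poisson interval, both at 95%. The labels name no molecular identifiers, so intervals cover counting error only. A gene with 0 counts in a library was given a bound computed with 3 counts in its place, which takes the other count as exact, and the limit of the exact interval is given beside it. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.

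Gene lists were fixed before the data were examined, from textbook knowledge of adipose stroma, as were the settings, the alternatives and the rule for named genes. There were 28 lists written out gene by gene plus ribosomal protein genes by symbol. Mitochondrial transcripts were to be found by the prefix mt-, which the table does not use, so a list of the 13 protein-coding mitochondrial genes by their names in the table was added after the data were seen. A list's median log2 fold was placed among medians of 10000 random lists of equal size, drawn within 20 bins of mean expression. A list with at least 5 measured members stood apart when its percentile was under 2.5 or over 97.5. This describes these libraries, since genes are not replicates. Named genes were Sox9, Meis1, Dlk1, Pdgfra, Pparg, Cebpa, Cebpb, Cebpd, Zfp423, Fabp4, Adipoq, Ly6a, Cd34 and Mki67, the 10 highest and 10 lowest log2 folds among genes with 100 or more counts in the larger library without predicted symbols, and the 3 members with the largest absolute log2 fold of each study or cell type list. Some of these members are not reported here. A few further genes were chosen after their values were seen. In the results these are Pbx3, Pknox1, Vcam1, Icam1, Cd44, Sfrp4, Lef1, Col3a1, Fn1, Thbs1, Lyz2, Csf1r, COX1 and Xist. The others are named so in the closing section.

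The calculation was tested on simulated data. Counts were drawn for the 18911 genes of the PreASKO and floxed comparison at equal levels, except 200 genes changed 4-fold. The changed genes were picked from those with an expected floxed count of 200 or more, so recovery of lower genes was not tested. All of the changed genes passed the 2-fold limit in the right direction, 0 unchanged genes passed it, and 95.2% of exact intervals held the true ratio. Of 400 random lists of 20 genes from the real folds, 6.00% fell outside the percentile limits, and of 100 such lists lowered by 0.5 in log2, 93.0% were found. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter 5 times stricter, scaling by median of ratios (DESeq2 1.42.0), by upper quartile and by total, thresholds of 1.5-fold and 3-fold, list means, and random lists not matched on expression. Added after the data were seen were raw counts alone (for named genes, where 1 library had 20 or more), repeat-distributed counts alone, the authors' deposited fold, and scaling to the stromal matrix list. No sample and no measured column of the table was left out.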

Results

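RNA sequencing was carried out on GFP+ cells of the stromal vascular fraction from the inguinal fat pad of mice. This fraction is the mixture of cells other than fat-laden adipocytes that collagenase releases from subcutaneous white fat. The series' design text equates the GFP+ cells with Pref-1+ cells. Pref-1 is the product of Dlk1 and marks early adipose precursors. The mice were males 3 weeks of age that had received doxycycline on postnatal day 1. The 2 libraries were 1 from Sox9 floxed mice and 1 from Sox9 PreASKO mice, which the labels also title KO. Each library pooled cells of several mice. The design text gives the pool as 6 without saying whether that is per genotype, so no difference between the libraries has a replicate check. The floxed library held 37705236 counts and the PreASKO library 29172653, over 24862 listed genes. Intervals in parentheses are exact 95% intervals that cover counting error only.

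Sox9, the transcription factor gene targeted in these mice, was 2.36-fold lower in the PreASKO library (1.80 to 3.11). Its level in CPM, the count scaled to a common library size, was 5.97 CPM in the floxed library and 2.53 CPM in PreASKO, from 228 and 73 counts. Meis1, a homeobox gene that the series title names together with Sox9, was 1.94-fold lower (1.58 to 2.40), at 8.77 CPM in floxed cells and 4.51 CPM in PreASKO cells. Among other homeobox genes of the same families, Meis2 stood at 15.8 CPM in floxed cells and 9.13 CPM in PreASKO cells. Pbx3 and Pknox1 had log2 folds of 0.66 and -0.03, and the list of 9 Meis, Pbx and Pknox genes had a median log2 fold of -0.03, at percentile 45.7 of random lists matched on expression.

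The comparison asks which genes differ between Sox9 floxed and Sox9 PreASKO GFP+ cells by more than 2-fold, and the title raises Sox9 and Meis1 as the genes of interest. Sox9 (gene ID 20682) lies on chromosome 11 from 112782210 to 112787757 in GRCm38, and Meis1 (gene ID 17268) lies on chromosome 11 from 18880428 to 19019651. The level of Sox9 was summed over the whole gene. The labels do not say which exons are floxed, so reads from exons that remain after recombination would count as Sox9, and the value is a partial check of the deletion. On the log2(CPM + 1) scale the folds were -0.98 for Sox9 and -0.83 for Meis1, which places both within the 2-fold limit on that scale. Raw counts alone, scaled by their own totals, gave -1.09 and -1.02, past the limit. All counts of Sox9 are raw, however, and its ratio was 0.426 in raw and 0.424 in summed counts. Its lower value reflects the smaller totals, which give the pseudocount less weight. The authors' deposited log2 folds, of another scale, were -1.27 and -1.40, each past the limit. Relative to the median of the stromal matrix genes described below, the folds were -0.46 for Sox9 and -0.25 for Meis1.

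**Figure D1:**
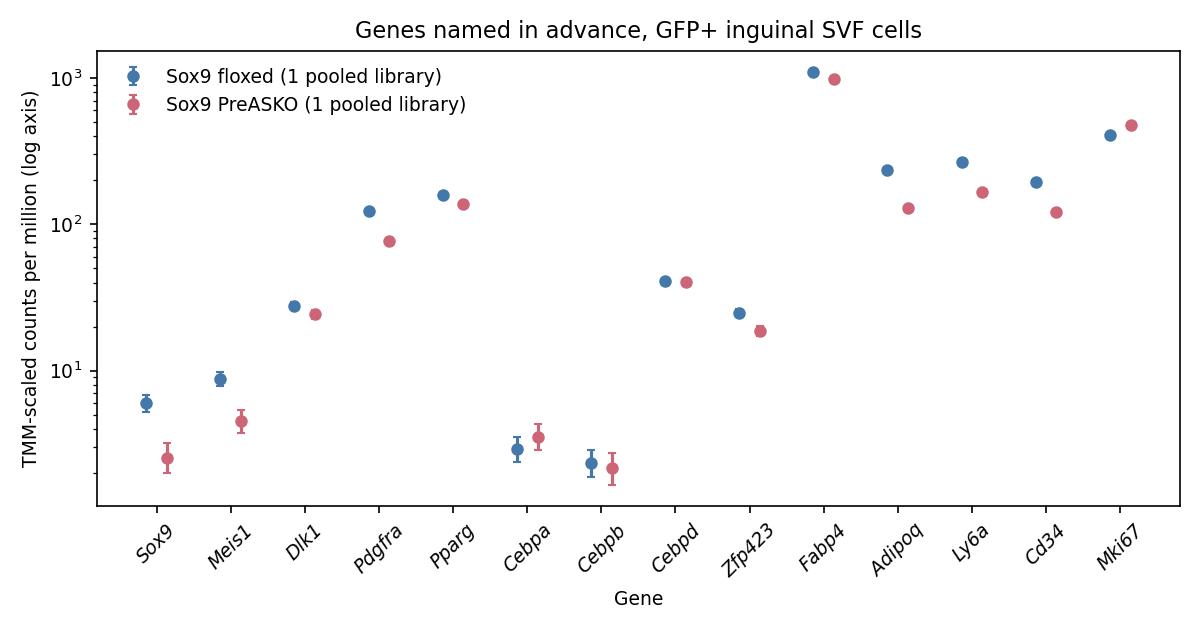
Levels of the 14 genes named in advance in the Sox9 floxed and Sox9 PreASKO libraries, in TMM-scaled CPM on a log axis, with exact 95% Poisson intervals for counting error (1 pooled library per group). Sox9 lies at 5.97 and 2.53 CPM and Meis1 at 8.77 and 4.51 CPM, while Cebpd lies at 40.7 and 40.2 CPM.

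Markers of adipose precursors were mostly lower in PreASKO. Pdgfra, a receptor on committed adipose precursors, stood at 124 CPM in floxed cells and 77.0 CPM in PreASKO cells, a ratio of 0.623 (0.592 to 0.655). Ly6a, which encodes Sca-1, had a ratio of 0.623 (0.602 to 0.645) and Cd34 one of 0.620 (0.595 to 0.645). Dpp4 and Pi16, which mark an interstitial precursor population, had ratios of 0.282 (0.256 to 0.310) and 0.436 (0.421 to 0.451). Dlk1 itself differed less, at 27.9 and 24.3 CPM, a ratio of 0.872 (0.791 to 0.960). Raw counts alone, 160 in floxed and 129 in PreASKO cells, gave a log2 fold of 0.09, for which no interval was computed. Of 19 precursor and stromal surface genes, 14 were lower and 5 higher in PreASKO. The higher ones included the adhesion molecule genes Vcam1, with a ratio of 1.53, and Icam1 and Cd44, each with a ratio of 1.42. The median log2 fold of the list was -0.38, below all 10000 random lists (percentile 0).

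Adipogenic transcription factor genes did not move one way. Pparg, the main regulator of adipocyte differentiation, stood at 159 and 137 CPM in floxed and PreASKO cells, a ratio of 0.861 (0.827 to 0.897). For Cebpa the ratio was 1.22 (0.922 to 1.61), for Cebpb 0.923 (0.657 to 1.29) and for Cebpd 0.989 (0.916 to 1.07), each within counting error of equal levels. Zfp423, a factor of preadipocyte commitment, had a ratio of 0.748 (0.672 to 0.832). Klf5 was lower, from 147 to 15 counts, and so was Ebf2, with a ratio of 0.393, whereas Klf15 had a ratio of 2.40 (1.99 to 2.91). The median of the 18 factors was -0.05, at percentile 24.3.

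Adipocyte and lipid storage genes were lower as a group, with 26 of 34 below equal levels, a median log2 fold of -0.37 and percentile 0. Adipoq, which encodes the adipocyte hormone adiponectin, had a ratio of 0.550 (0.530 to 0.572). Fabp4, a fatty acid binding protein gene, stood at 1096 and 978 CPM, a ratio of 0.892 (0.879 to 0.906), while raw counts alone gave a log2 fold of 0.10. Fasn, the fatty acid synthase gene, stood at 293 CPM in floxed cells and 147 CPM in PreASKO cells, and Elovl6, a fatty acid elongase gene, at 9.66 and 3.12 CPM. Slc2a4, the insulin-responsive glucose transporter gene, had a ratio of 0.402. Of 12 thermogenic genes, 9 were lower. Elovl3, with 27 counts in floxed cells and 0 in PreASKO cells, was at least 6.79-fold lower against a floor of 3 counts (limit of the exact interval 5.15), and Tbx1 had a ratio of 1.97. The thermogenic median of -0.21, at percentile 10.6, did not stand apart from random lists.

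Genes of the extracellular matrix were lower almost throughout. Of 31 collagen and stromal matrix genes, 29 were lower in PreASKO, with a median log2 fold of -0.68 (percentile 0), and together they held 5.64% of floxed and 3.43% of PreASKO counts. Col3a1, a fibrillar collagen, stood at 9650 CPM in floxed cells and 5336 CPM in PreASKO cells. Postn, which encodes periostin, had a ratio of 0.433 (0.427 to 0.440), and Lox, the collagen cross-linking enzyme, one of 0.460. Fn1 and Thbs1 were the exceptions, with ratios of 1.03 and 1.38. Matrix proteases and their inhibitors were lower in 13 of 17, with a median of -0.60 (percentile 0). Adamts1 and Adamts4 had ratios of 0.380 and 0.355, whereas Mmp13, a collagenase gene, had a ratio of 2.70.

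All 10 Hedgehog pathway genes were lower, with a median log2 fold of -0.99 (percentile 0). Gli2, a transcription factor of the pathway, had a ratio of 0.340, the coreceptor gene Cdon 0.400 and the receptor gene Ptch1 0.412. Wnt pathway genes were lower in 19 of 24, with a median of -0.59 (percentile 0.03). The ligand gene Wnt5a went from 356 to 34 counts and Wnt11 from 134 to 14, while the secreted antagonist genes Sfrp2 and Sfrp4 had ratios of 0.363 and 0.375. Lef1, a transcription factor of Wnt signalling, had a ratio of 2.60. Random lists matched on expression do not account for the share of stromal cells, and the stromal matrix median was -0.68. The Sox9 and cartilage list had a median of -0.45 over 16 genes, at percentile 3.16, and so did not stand apart. Within it Col2a1, a collagen gene that Sox9 is known to activate in cartilage, went from 190 to 18 counts and Fmod from 728 to 137, while Prg4, which encodes lubricin, went from 1873 to 7284. The TGF-beta and BMP list had a median of -0.29 over 21 genes, at percentile 2.73. Its members included Inhba and Fst, with ratios of 0.209 and 0.436, and Id1, with a ratio of 2.96. Both of the last lists passed the limit of 2.5 under some other settings.

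Markers of other cell types differed alongside these groups. All 22 macrophage and myeloid markers were higher in PreASKO, with a median log2 fold of 0.58 (percentile 100), and together they held 2.04% of floxed and 3.13% of PreASKO counts. Lyz2, the lysozyme gene of macrophages, stood at 2579 and 4463 CPM in floxed and PreASKO cells and Csf1r, their growth factor receptor gene, at 1600 and 2596 CPM. The antigen presentation genes H2-Ab1 and Cd74 had ratios of 2.21 and 1.99, and the scavenger receptor gene Cd163 one of 2.01. These genes were abundant in both libraries. Granulocyte and mast cell markers were higher in 12 of 13, with a median of 0.87 (percentile 100), and all 7 measured erythroid markers were higher, with a median of 1.07 (percentile 100). The haemoglobin genes Hbb-bt, Hba-a1 and Hbb-bs had ratios of 2.19, 2.16 and 2.12. Lymphocyte markers had a median of 0.27 over 18 genes (percentile 97.55), with Cd3d at a ratio of 1.79 and Lck at 1.67.

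Endothelial markers had a median log2 fold of 0.19 over 17 genes (percentile 83.5), with ratios of 1.74 for Vwf, 1.57 for Flt1 and 0.672 for Tek. Mural and smooth muscle markers had a median of -0.33 over 15 genes (percentile 1.53). Abcc9 had a ratio of 0.508, Acta2 one of 0.615 and Myh11 one of 0.632. Mesothelial and epithelial markers were the lowest list. All 13 measured members were lower in PreASKO, 10 of them by over 2-fold, with a median of -2.65 (percentile 0). Without the pseudocount, and with members at 0 set to 3 counts, the median log2 ratio was -4.77. The skeletal muscle list had a median of -0.26 (percentile 18.7), with Myl1 at a ratio of 0.420, Des at 0.497 and Myh4 at 2.97. The Schwann cell and neural list had a median of 0.14 (percentile 84.2), with L1cam at a ratio of 2.33 and Sox10 at 3.67.

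**Figure D2:**
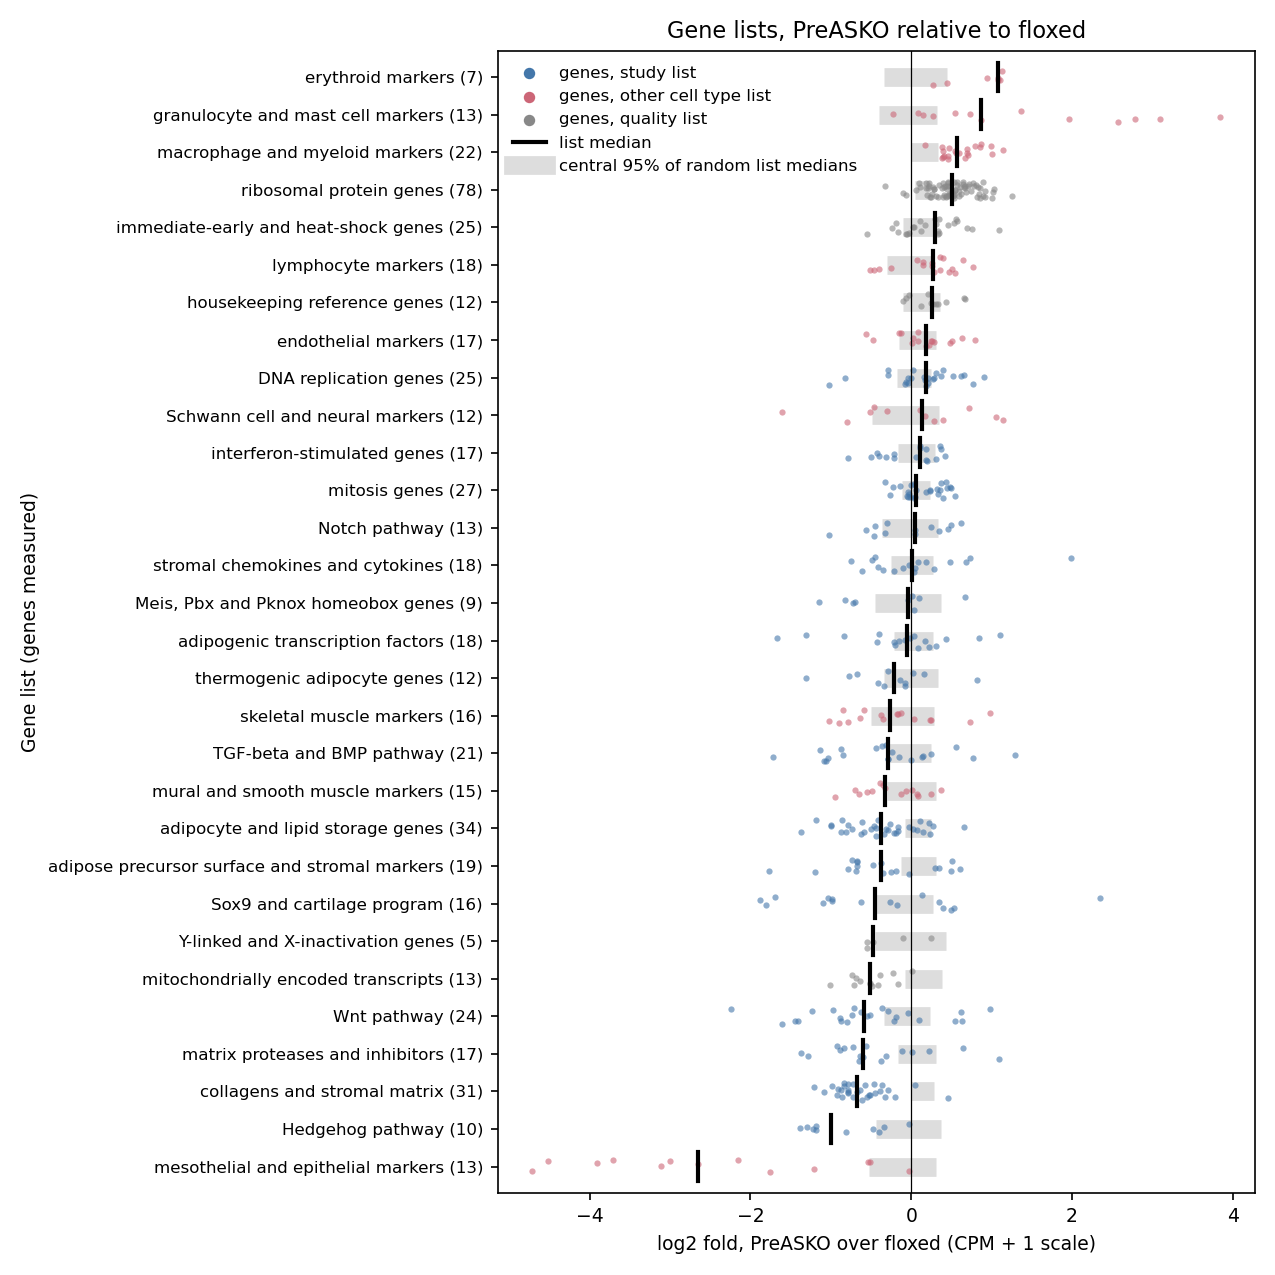
Log2 folds of PreASKO over floxed on the CPM + 1 scale (horizontal axis) for the measured members of each gene list (vertical axis, number of genes in parentheses). Points are genes, coloured by the kind of list, black bars are list medians, and grey bars hold the central 95% of medians of random lists matched on expression. Mesothelial and epithelial markers have the lowest median (-2.65) and erythroid markers the highest (1.07).

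Proliferation genes went both ways, and neither the mitosis nor the DNA replication list stood apart from random lists. Mki67, a marker of cycling cells, stood at 407 CPM in floxed cells and 479 CPM in PreASKO cells, a ratio of 1.18 (1.15 to 1.21). Of 27 mitosis genes, 17 were higher and 10 lower, with a median of 0.07 (percentile 49.8). Nusap1 had a ratio of 1.47, Ube2c one of 1.42 and Cdc20 one of 1.41. The list of 25 DNA replication genes, 17 higher and 8 lower, had a median of 0.19 (percentile 92.1). Its members diverged, with the licensing factor gene Cdt1 at a ratio of 1.94 and E2f1 and Ccne1, which act at entry into S phase, at 0.413 and 0.463. The Notch list had a median of 0.04 (percentile 58.2), with Hey1 at a ratio of 0.271, Hey2 at 0.379 and Notch4 at 1.64. Chemokine and cytokine genes of stroma had a median of 0.00 (percentile 44.3), with the acute-phase gene Saa3 at a ratio of 4.54, Lcn2 at 1.73 and Cxcl12 at 0.574. Interferon-stimulated genes had a median of 0.11 (percentile 59.4), and Ifit1, Ifit3 and Oas2 had ratios of 0.557, 0.694 and 0.744. Raw counts alone gave Oas2 a log2 fold of 0.05.

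Among genes with 100 or more counts in the larger library, the lowest in PreASKO were mostly genes of mesothelium and epithelium. Msln, which encodes mesothelin, went from 1104 counts in floxed cells to 4 in PreASKO cells, 208-fold lower (81.1 to 766). Upk3b was 48.2-fold lower (32.6 to 74.8), the keratin gene Krt19 27.3-fold lower (19.3 to 39.9), Lrrn4 18.6-fold lower (14.5 to 24.2) and the mucin gene Muc16 61.4-fold lower (29.6 to 154). The uroplakin gene Upk1b, with 292 counts against 0, was at least 73.4-fold lower against a floor of 3 counts (limit of the exact interval 59.4). The sulfotransferase gene Chst4, with 216 against 0, was at least 54.3-fold lower (limit 43.8). Krt14, with 279 counts against 1, had a ratio of 0.00475 (0.00012 to 0.0267). Rspo1, a secreted enhancer of Wnt signalling, was 16.9-fold lower and the ferric reductase gene Cybrd1 14.9-fold lower.

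The highest genes in PreASKO included several neutrophil genes. Camp, which encodes cathelicidin, went from 20 to 602 counts, a ratio of 39.9 (25.6 to 65.8). Ngp had a ratio of 13.8 (10.4 to 18.5), S100a9, a calgranulin gene, 8.88 (7.28 to 10.9), and Padi4, whose enzyme citrullinates histones, 10.1 (8.04 to 12.8). The chitinase-like gene Chil1 had a ratio of 26.0 (15.5 to 47.0), the fatty acid receptor gene Gpr84 one of 12.0 (8.41 to 17.7) and Myrip one of 11.3 (8.11 to 16.2). Alox15, a lipoxygenase gene, was the most abundant of this group, at 50.3 CPM in floxed cells and 377 CPM in PreASKO cells. Ighg1, an immunoglobulin heavy chain gene, had 4 counts in floxed cells and 533 in PreASKO cells, a ratio of 177 (68.6 to 650). Il4i1, an amino acid oxidase gene, had 0 and 1717 counts. It was at least 758-fold higher against a floor of 3 counts (limit of the exact interval 616). All of its counts were repeat-distributed, as in many genes with several annotated transcripts such as Pdgfra and Postn. Il4i1 has 1 RefSeq transcript, however, and only 3.31% of such genes had repeat-distributed counts alone, so its value is uncertain.

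**Figure D3:**
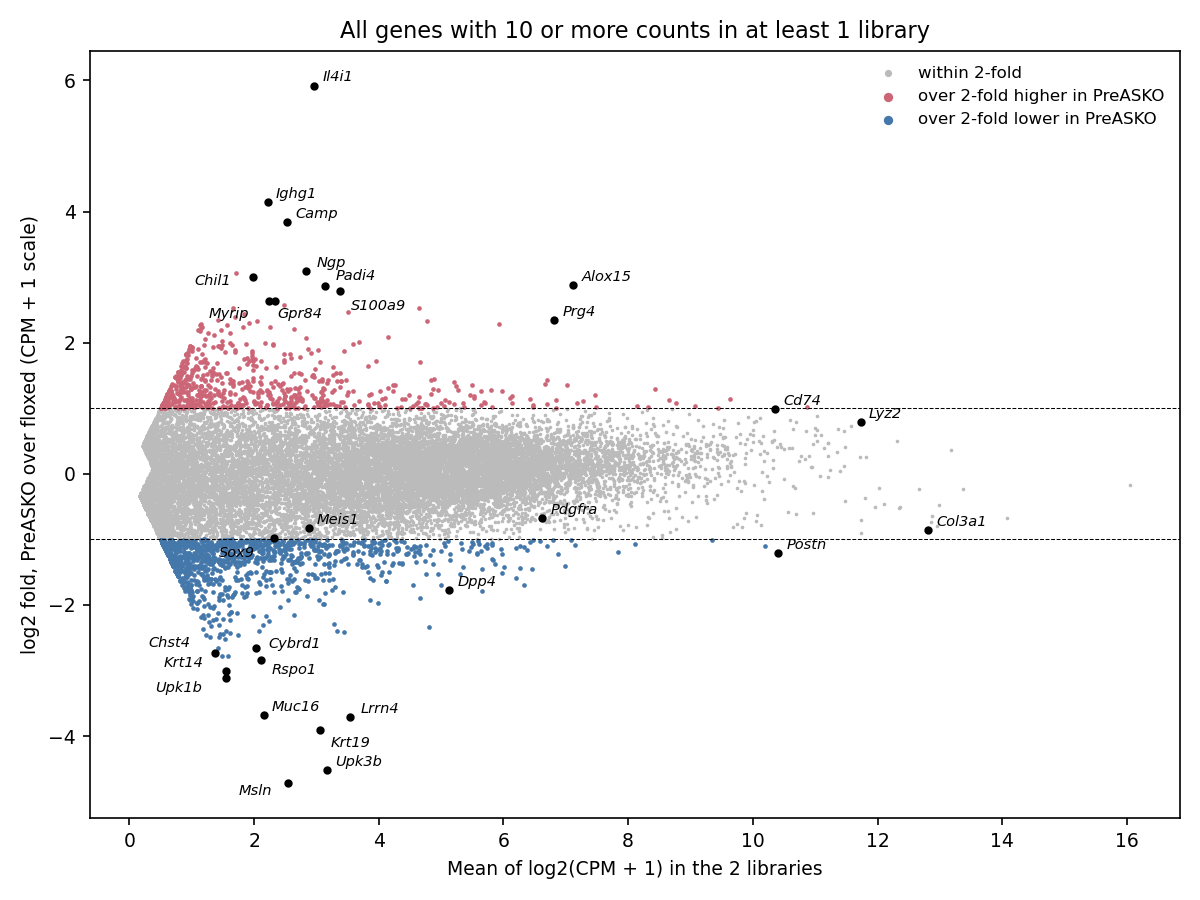
Log2 fold of PreASKO over floxed against the mean of log2(CPM + 1) in both libraries, for the 18911 genes with 10 or more counts in at least 1 library. Coloured points lie over 2-fold apart on the CPM + 1 scale, 645 higher and 1061 lower in PreASKO, and black points are labelled genes such as Msln (-4.72) and Il4i1 (5.92).

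Over all genes, 645 were more than 2-fold higher and 1061 more than 2-fold lower in PreASKO, out of 18911 with 10 or more counts in at least 1 library. Of the 12982 genes with 100 or more counts in the larger library, 365 were higher and 706 lower, and of the 5907 with 1000 or more, 68 were higher and 107 lower. Counts redrawn with equal levels in both libraries gave 0 genes past the limit in each of 100 draws, a comparison of these libraries and not of the genotypes. The draws hold counting error only, and the pseudocount of 1 keeps the lowest genes inside the limit. They cannot say how many genes would pass between like libraries. With a pseudocount of 0.1 in place of 1 the counts were 1672 and 3146, and with 5 they were 101 and 142. In the authors' deposited table, the fold column exceeded 2-fold for 1735 higher and 3457 lower genes of the same 18911.

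Quality lists also differed between the libraries. Ribosomal protein genes were higher in 75 of 78, with a median log2 fold of 0.51 (percentile 100). The 13 mitochondrially encoded transcripts had a median of -0.51 (percentile 0) and held 14.4% of floxed and 11.0% of PreASKO counts. COX1 alone took 7.29% and 6.35%. Immediate-early and heat-shock genes had a median of 0.30 over 25 genes (percentile 98.4), and 12 housekeeping genes one of 0.26 (percentile 84.2). The list of 5 Y-linked and X-inactivation genes had a median of -0.48 (percentile 1.98), with 4 lower and 1 higher. That median is the value of Xist, an X-linked gene with 15 counts in floxed cells and 0 in PreASKO cells. In all, 15 of the 29 lists fixed in advance stood apart from random lists, 9 lower and 6 higher. Independent draws of genes would give 1.45. Genes of a list can move together and some lists share members, so 1.45 does not measure chance between the libraries. The lymphocyte, mural, immediate-early and Y-linked lists came back inside the percentile limits under some other settings.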

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

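The scaling to the stromal matrix list, raw or repeat-distributed counts alone and the authors' deposited fold were settings chosen after the data were seen. With 1 pooled library per group, no replicate could be left out, and depth limits genes with few counts. Under other pseudocounts or median-of-ratios scaling no list that stood apart, and no named gene whose interval excluded equal levels, reversed direction, nor did lists with a stricter filter, means or unmatched random lists. Raw counts alone changed the sign of the log2 folds of Dlk1 (-0.19 to 0.0914), Fabp4 (-0.16 to 0.0976) and Oas2 (-0.42 to 0.0455). Dlk1 had only 160 raw counts in floxed cells and 129 in PreASKO cells, Oas2 had 1671 and 1296, and Fabp4 had 16671 and 13401. No interval was computed for these raw folds, so those of Dlk1 and Oas2 may lie within counting error of equal levels. The raw counts of Fabp4 are too many for that, so its direction depended on the type of count. The cause of the sign changes was not tested. Lists were not run on raw counts. Scaling to the matrix list was run for Sox9 and Meis1 only, and since the matrix median was -0.68, genes lower by less would come out higher by construction. Under median-of-ratios, upper-quartile or total scaling, with no filter or a stricter one, and with raw or repeat-distributed counts alone, the numbers of genes past 2-fold stayed within 1.5 times of 645 higher and 1061 lower. They became 1672 and 3146 with a pseudocount of 0.1, 101 and 142 with one of 5, 129 and 198 at 3-fold, 2167 and 3055 at 1.5-fold, and 1735 and 3457 by the authors' deposited fold. A smaller pseudocount or threshold lets more low genes pass by construction. The log2 fold of Sox9 moved from -0.98 to -0.54 with a pseudocount of 5 and to -0.46 when scaled to the matrix list, and that of Meis1 from -0.83 to -0.25 when so scaled and to -1.40 by the authors' deposited fold. The cause of the last was not tested. Raw counts alone, scaled by their own totals, put both past 2-fold (-1.09 and -1.02). For Sox9 these are the same counts, and only the weight of the pseudocount changed. Over the named genes, each shift was compared with the mean distance of the counting interval's limits from the log2 ratio. Under other settings 378 values moved by no more than that and 78 by more. Genes with 0 counts in 1 library have no finite distance and fell among the 378 whatever their shift.

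For lists, 154 values kept their side of the limits. Some lists came to stand apart, and the cause was not tested. The Sox9 and cartilage list did so with medians of -0.97 (pseudocount 0.1), -0.21 (pseudocount 5), -1.01 (stricter filter) and -0.45 (unmatched random lists). The TGF-beta and BMP list did so at -0.22 (pseudocount 5), -0.29 (stricter filter) and -0.32 (mean). Other lists no longer stood apart, again without a tested cause. These were immediate-early and heat-shock genes at 0.26 (pseudocount 5) and 0.23 (mean), lymphocyte markers at 0.19 (pseudocount 5), 0.27 (stricter filter) and 0.20 (mean), and mural markers at -0.20 (pseudocount 5), -0.26 (mean) and -0.33 (unmatched). Y-linked and X-inactivation genes joined them at -0.56 (pseudocount 0.1), -0.11 (pseudocount 5), -0.29 (mean) and -0.48 (unmatched).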

Other observations

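All tests in this part were chosen after the results were seen, and so were the genes named in the next paragraph.

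F5, which encodes a coagulation factor, went from 425 to 1734 counts, a ratio of 5.41 (4.86 to 6.03), and Serpinb2, an inhibitor of plasminogen activators, had a ratio of 3.22 (2.70 to 3.85). Timd4, a receptor gene of resident macrophages, stood at 507 CPM in floxed cells and 857 CPM in PreASKO cells. The immunoglobulin gene Ighg2b had a ratio of 6.29 (5.61 to 7.06). Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 222 and 451 CPM, a ratio of 2.03 (1.98 to 2.09). Among neutrophil genes, Ltf, which encodes lactoferrin, and the calgranulin gene S100a8 had ratios of 9.79 (7.25 to 13.5) and 11.7 (6.74 to 22.1). Cxcr2, a chemokine receptor gene, had a ratio of 2.60 (2.47 to 2.73) and Retnlg one of 1.76, while Csf3r, the receptor gene for granulocyte colony-stimulating factor, had one of 0.851 (0.783 to 0.925). Nup62, which lies next to Il4i1 on chromosome 7, had 1640 counts in floxed cells and 1143 in PreASKO cells, a ratio of 0.924 (0.856 to 0.997). Ucp1, the uncoupling protein gene of thermogenic fat, had a ratio of 0.789 (0.773 to 0.805), from 25976 and 15461 counts. The Y-linked genes Ddx3y, Uty and Kdm5d had ratios of 0.654, 0.676 and 1.19. Xist, the RNA of the inactive X chromosome, had 15 counts in floxed cells and 0 in PreASKO cells.

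Lower stromal matrix, precursor and adipocyte genes went with higher myeloid genes. A smaller share of stromal cells with nothing else altered would raise the markers of other cell types alike. The myeloid list median lay 0.38 in log2 above the endothelial one, with a 95% bootstrap interval over members of 0.21 to 0.66. For these libraries, that argues against a smaller stromal share as the whole account. A larger share of myeloid cells alone would lower stromal and endothelial markers alike, yet the stromal matrix median differed from the endothelial one by -0.87 (-1.04 to -0.60). Both intervals cover spread over list members, not between libraries or mice. They bear on the make-up of these libraries and not on the genotypes. How far selection of GFP+ cells removed myeloid cells was not measured, and their genes were abundant in both libraries. Shifts in several cell types together, and differences within cells of the genotypes, may both contribute and remain open with 1 library per genotype.

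Sox9 and Meis1 were lower in the library in which stromal genes were lower, and for Meis1 the ratio of 0.514 (0.417 to 0.632) covered the stromal matrix median of 0.624, and 16 of 31 matrix genes lay at or below its upper limit. In raw counts alone its ratio of 0.415 (0.280 to 0.601) excluded their median of 0.603, though 10 of 20 lay at or below its upper limit, and its deposited fold of 0.379 was below that of each matrix gene. For Sox9 the ratio of 0.424 (0.321 to 0.555) excluded the summed-count median of 0.624 and 0 of the 31 matrix genes had a lower ratio, but 7 of the 31 lay at or below its upper limit. Raw counts, which are all of its counts, gave 0.426 (0.323 to 0.557), which also excluded the raw median, with 5 of 20 at or below the upper limit, and its deposited fold of 0.414 was below that of each matrix gene. A lower level within cells and a smaller share of stromal cells therefore cannot be told apart for Sox9 or Meis1, because the cells that carry them were not measured separately. Other changes in make-up, such as the near lack of mesothelial and epithelial genes in PreASKO, were not weighed for either gene.

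Mesothelial and epithelial genes were nearly lacking in PreASKO, where 10 of the 13 measured members of the list were over 2-fold lower and 0 over 2-fold higher, and 4 of the 7 members outside the 10 lowest genes were over 2-fold lower. That count restates the pattern, so it cannot be told apart whether such cells were taken along in the floxed library or lost through the genotype, with 1 library per genotype. How far selection of GFP+ cells removed such cells was not measured. The most abundant members stood at 41.9 CPM (Upk3b), 41.3 CPM (Lrrn4) and 31.3 CPM (Krt19) in floxed cells. Wt1 is also expressed in some adipose stroma, but whether stroma of the inguinal depot expresses it was not tested. Raw counts, which are not shared out, argue against sharing of reads for the members they cover. Of members with 20 or more raw counts in floxed cells, 7 of the 7 were over 2-fold lower in raw counts alone by their whole interval. Msln, with 13 raw counts in floxed cells, and Lrrn4 and Upk1b, with 0 in both libraries, were not covered.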
